A study of Mus musculus with 24 samples.

How the data were processed

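RNA from peripheral blood of mice was measured on 24 one-colour Agilent mouse arrays. Per the labels, the blood came from male C57BL/6J mice labelled Gadd45aWT or Gadd45aKO, taken 24 h after exposure to 0 Gy or 7 Gy of x-rays. The groups held 5 Gadd45aWT arrays at 0 Gy, 5 Gadd45aWT arrays at 7 Gy, 5 Gadd45aKO arrays at 0 Gy and 9 Gadd45aKO arrays at 7 Gy. Here they are called WT and KO-labelled, because the probe for Gadd45a was not lower in the KO-labelled arrays. The design text speaks of independent experiments and no label names the animal behind an array, so the p-values measure the spread between these samples alone.

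Per the file headers, the authors' scanner files hold spot intensity from Agilent Feature Extraction 12.0.2: the processed signal is an intensity after background subtraction and spatial detrending within the array, with no scaling between arrays. Each deposited file lists 44397 spots, of which 43020 are not controls. The deposited value table holds log2 values for 12900 entries, 37 of them controls, and 0 columns of samples outside the series. Each of its columns was checked against the matching scanner file: the deposited log2 value equalled the log2 of the processed signal plus a constant of 0 to 1.54 per array, with values set to at least 10 before the logarithm. The medians of its columns were, for KO-labelled 0 Gy replicates 1 to 5, 5.93, 6.19, 6.36, 6.41 and 6.41; for KO-labelled 7 Gy replicates 1 to 9, 5.82, 6.09, 6.10, 6.53, 7.18, 6.37, 6.20, 5.81 and 6.23; for WT 0 Gy replicates 1 to 5, 5.75, 6.03, 6.39, 6.40 and 6.00; and for WT 7 Gy replicates 1 to 5, 5.87, 5.93, 6.30, 6.22 and 6.12. The dye field of some labels names another dye than the Cy3 of the labelling protocol; each array was read from its green channel, the one channel present.

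The log2 of each processed signal minus the array's 75th percentile, taken over the 7803 probes well above background on all 24 arrays, gave the values. Spots of the same probe were averaged. Of 39429 probes, the 19648 well above background on at least 5 arrays were kept, and the probe with the highest mean stood for each gene, which gave 15785 genes. Probes were named by the accession in the files (28663 probes), by symbol (3300), by an older symbol (160) or, failing these, by the name in the files (7306). Coordinates are those of mm9, the build in the file headers.

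Depth on an array is the signal over background. The share of probes well above background ran from 25.6% to 50.9% and the 75th percentile of the processed signal from 25.8 to 106.7. The number of arrays limits the precision. KO-labelled 0 Gy replicates 1 and 4 differed by no more than repeat spots within an array (ratio 0.98). Except in fits with a block, they were averaged and counted once, which left 23 units and n = 4 in that group. Repeat spots of 4 arrays varied by over 10%: KO-labelled 0 Gy replicate 2 (15.7%), WT 0 Gy replicate 1 (26.8%), and KO-labelled 7 Gy replicates 3 (16.5%) and 5 (11.1%).

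Differences were tested with limma 3.58.1 in R 4.3.3, with version 1.17.8 of data.table, in a single fit of the 4 groups, and called at a Benjamini-Hochberg adjusted p under 0.05. The fit gave the response to 7 Gy in WT, the response in KO-labelled arrays, the difference between these responses, and the KO-labelled against WT difference at 0 Gy and at 7 Gy. All p-values are two-sided, and errors of log2 changes are standard errors. Tables and figures used Python 3.11.15 with pandas 2.3.3, NumPy 2.4.6 and matplotlib 3.10.9.

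The gene lists covered p53 targets, human blood radiation biodosimetry, DNA repair, cell cycle, B cells, T cells, natural killer (NK) and cytotoxic cells, neutrophils, monocytes and macrophages, erythroid cells, platelets, interferon response, MHC class II, inflammatory cytokines and NF-kB, p38 and JNK kinases, oxidative stress, ribosomal proteins, oxidative phosphorylation, heat shock, and T cell activation and autoimmunity. Each of the 20 lists was tested in each comparison with camera at a preset correlation of 0.01, adjusted over all lists and comparisons, and again with an estimated correlation, with fry and with an exact permutation of the array means. The smallest p that the permutations can give is 0.00794 for WT, 0.0014 for KO-labelled arrays, 0.00794 at 0 Gy and 0.0005 at 7 Gy. Further lists were chosen after seeing the data: hepatocyte genes, hepatic acute phase genes, genes of lung, muscle, kidney, skin and pancreas, eosinophil genes and targets of ATF4.

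The lists, the threshold, the comparisons and the rule for named genes were fixed before the data were examined. In each comparison, the rule takes the 10 largest increases and the 10 largest decreases among called genes with a proper symbol. These genes had to be well above background on every array of a compared group and, between a pair of groups, show no overlap. The rule adds up to 4 called members of each list with the largest changes, and in every comparison Gadd45a, Cdkn1a, Mdm2, Ccng1, Phlda3, Aen, Bax, Trp53 and Myc. The text gives part of the genes that the rule names, chosen after their values were seen, and 2 are not reported here. Eda2r was on this list, but its 2 probes were well above background on 0 arrays.

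The fit was tested on simulated data with 200 changed genes among 15785. It recovered 74.2%, 86.4%, 54.5%, 75.8% and 78.8% of the genes changed by 4-fold in the 5 comparisons in the order above. At 2-fold it recovered 35.8%, 29.9%, 13.4%, 28.4% and 37.3%, at 1.5-fold 6%, 13.4%, 0%, 7.5% and 7.5%. It made 10, 4, 2, 4 and 4 false calls and called 0 lists. Genes and arrays were simulated as independent, so these counts do not cover errors from correlation between genes or between arrays.

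Alternatives covered background correction (normexp with an offset of 50), quantile and median scaling, the probe filter, the probe standing for a gene, the authors' value table, blocks by replicate number, slide or scan day, array weights, a fold threshold, fits on fewer groups and arrays, and leaving out each array in turn. Slides 1 to 5 each held 1 array per group, and slide 6 held KO-labelled 7 Gy replicates 6 to 9, so within-slide values compare arrays of slides 1 to 5. Arrays of a group whose log2 values differed by an SD under 0.25 formed 5 near-identical sets, and averaging each set left 13 units. The SD was estimated from the median absolute deviation over 6533 bright probes, and ratios to spot noise from 65 replicated probes. In KO-labelled arrays the sets were replicates 1, 3 and 4 at 0 Gy and 1, 2, 4 and 8 at 7 Gy. In WT they were replicates 2 to 5 at 0 Gy, 1 with 2 at 7 Gy, and 3 to 5 at 7 Gy. Averaging the sets and a fit without the 4 arrays with noisy repeat spots were chosen after seeing the data. So was a fit without WT 7 Gy replicates 3 to 5, which were highest in hepatocyte genes. It keeps only replicates 1 and 2 of that group.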

Results

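Transcripts of peripheral blood were measured on 24 arrays from 4 groups of male mice: 5 wild-type (WT) arrays at 0 Gy, 5 WT arrays at 7 Gy, 5 KO-labelled arrays at 0 Gy and 9 KO-labelled arrays at 7 Gy. The series studies Gadd45a, a gene induced by DNA damage, as a suppressor of autoimmunity and in blood tests of radiation dose. The share of probes well above background was 36.8% to 48.9% in WT at 0 Gy, 39.2% to 45.9% in WT at 7 Gy, 26.1% to 48.1% in KO-labelled arrays at 0 Gy and 25.6% to 50.9% in KO-labelled arrays at 7 Gy. In the KO-labelled group at 0 Gy, n = 4, because replicates 1 and 4 were counted once.

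Gadd45a was compared between genotype labels to see whether its transcript was lower where the label says knockout. At 0 Gy its level was 0.67 ± 0.24 (log2 relative to the 75th percentile of the array; SD, n = 5) in WT and 0.52 ± 0.16 (SD, n = 4) in KO-labelled arrays, a difference of −0.15 ± 0.21 (SE; limma adjusted p = 0.853). After 7 Gy it was −1.19 ± 0.32 (SD, n = 5) in WT and 0.02 ± 0.34 (SD, n = 9) in KO-labelled arrays, higher by 1.21 ± 0.17 in the KO-labelled arrays (2.31-fold, adjusted p = 4.76e-05). Its only probe lies at 66985376 to 66985435 on chromosome 6 (mm9, transcript of the RefSeq entry in the files) and was well above background on all 24 arrays. Gadd45a fell by 1.86 ± 0.20 after 7 Gy in WT (3.64-fold lower, adjusted p = 2.76e-07). In KO-labelled arrays it fell by 0.50 ± 0.19 (1.42-fold lower, adjusted p = 0.0324), a call that ended with median scaling (adjusted p = 0.577), the authors' value table (0.377) and near-identical arrays averaged (0.168), and without replicate 3 (0.0637) or 5 (0.0839) at 0 Gy or replicate 3 at 7 Gy (0.0526). The directions given for KO-labelled arrays follow the label alone, since the probe does not separate the genotypes at 0 Gy.

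**Figure D1:**
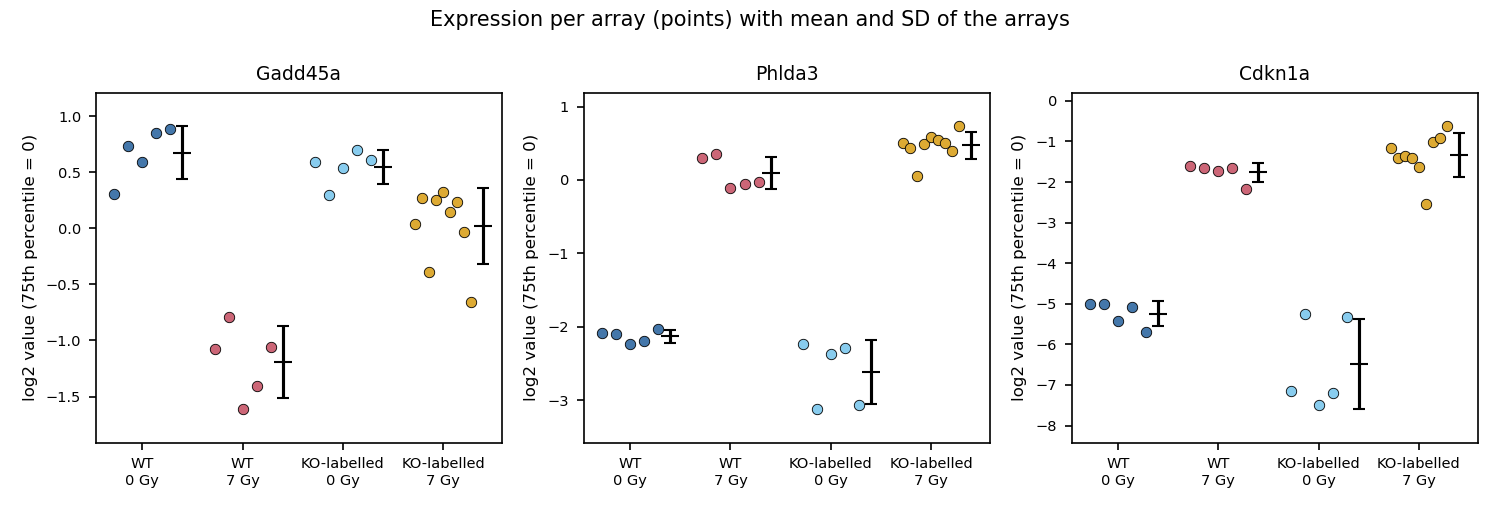
Log2 value of Gadd45a, Phlda3 and Cdkn1a relative to the 75th percentile of each array, by group, with each point an array and the bar the mean and SD of the arrays. Gadd45a of KO-labelled arrays at 0 Gy lies between 0.30 and 0.70, inside the 0.31 to 0.89 of WT arrays but for 1 array, while Phlda3 and Cdkn1a are higher in every array at 7 Gy than in any at 0 Gy.

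The WT arrays at 7 Gy (n = 5) were set against those at 0 Gy (n = 5) to find the blood transcripts that mark the exposure 24 h later. Genes of the p53 pathway rose: Cdkn1a, an inhibitor of cyclin-dependent kinases, by 3.47 ± 0.38 (log2, SE; 11.1-fold, adjusted p = 3.42e-07) and Phlda3, a repressor of Akt, by 2.22 ± 0.17 (4.67-fold, 3.21e-09). Ifit3, an antiviral gene induced by interferon, rose by 5.61 ± 0.31 (48.8-fold, 8.9e-11). Fcmr, the receptor for IgM on B cells, fell by 5.51 ± 0.44 (45.5-fold lower, 4.36e-09). The largest increases were of genes made by the liver: Saa2, an acute phase protein, was at least 528-fold higher (5.64e-10), albumin (Alb) at least 525-fold (4.71e-07), and Serpina1a, a protease inhibitor of plasma, rose by 9.72 ± 0.97 (1.17e-07) with 2 of 5 arrays at 0 Gy near background.

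Of 33 p53 targets, 23 rose and 2 fell (26 and 2 adjusted over the list alone). On average p53 targets changed by 1.50 ± 0.14 (2.83-fold, adjusted p = 6.42e-17, and adjusted p = 0.0257 with an estimated correlation) and by 1.42 to 1.55 within slides. Ccng1, a cyclin induced by p53, rose by 2.16 ± 0.20, Aen, an exonuclease, by 2.03 ± 0.21, and Bax, a promoter of apoptosis, by 1.69 ± 0.19. Mdm2, the ligase that degrades p53, rose by 1.07 ± 0.19 (adjusted p = 0.000187), a call that ended when near-identical arrays were averaged (0.182), while Trp53 changed by −0.74 ± 0.28 (0.0583) and Myc by −0.65 ± 0.50 (0.404) without passing the test. The Myc value rests on WT 0 Gy replicate 1, where Myc was near background, and was −1.23 without it (0.0221). Of 30 interferon response genes, 24 rose (26 adjusted over the list alone). On average interferon response genes changed by 2.05 ± 0.13 (4.14-fold, adjusted p = 1.34e-22, and adjusted p = 0.00368 with an estimated correlation) and by 1.70 to 2.24 within slides. Oas2, which makes the activator of RNase L, rose by 3.97 ± 0.32 and Rtp4, a negative regulator of the pathway, by 3.89 ± 0.29. Of 19 NK and cytotoxic markers, 9 rose (11 adjusted over the list alone). On average NK and cytotoxic markers changed by 0.84 ± 0.14 (adjusted p = 3.32e-07, and adjusted p = 0.17 with an estimated correlation) and by 0.51 to 1.28 within slides. Gzmb, a granule protease, rose by 2.13 ± 0.19. Of 22 platelet markers, 13 rose (16 adjusted over the list alone). On average platelet markers changed by 0.78 ± 0.18 (adjusted p = 1.07e-07, and adjusted p = 0.323 with an estimated correlation) and by 0.60 to 0.91 within slides. The clotting factor F5 rose by 1.15 ± 0.15, a call that ended when near-identical arrays were averaged (adjusted p = 0.0992). Of 23 biodosimetry genes, 10 rose and 5 fell (10 and 6 adjusted over the list alone). On average biodosimetry genes changed by 0.45 ± 0.13 (adjusted p = 0.0212, and adjusted p = 0.502 with an estimated correlation) and by 0.19 to 0.84 within slides. Their median was −0.11, opposite in sign to the mean and to the test. Zmat3, a p53 target among them, rose by 2.30 ± 0.23, with 3 of 5 arrays at 0 Gy well above background, and Pou2af1, a coactivator of B cells, fell by 4.48 ± 0.51.

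Of 22 B cell markers, 22 fell (22 adjusted over the list alone). On average B cell markers changed by −3.95 ± 0.26 (15.4-fold lower, adjusted p = 7.71e-24, and adjusted p = 0.0119 with an estimated correlation) and by −4.46 to −3.28 within slides. Of 10 MHC class II genes, 9 fell (10 adjusted over the list alone). On average MHC class II genes changed by −3.14 ± 0.27 (8.83-fold lower, adjusted p = 8.75e-12, and adjusted p = 0.055 with an estimated correlation) and by −3.41 to −2.76 within slides. H2-Ob, which tunes peptide loading in B cells, fell by 3.92 ± 0.31, a call that normexp correction ended (adjusted p = 0.0591). Of 30 erythroid markers, 1 rose and 17 fell (1 and 18 adjusted over the list alone). On average erythroid markers changed by −1.45 ± 0.21 (2.74-fold lower, adjusted p = 1.19e-07, and adjusted p = 0.265 with an estimated correlation) and by −1.81 to −0.87 within slides. Slc4a1, the anion exchanger of red cells, fell by 3.33 ± 0.35. Of 24 cell cycle genes, 10 fell (11 adjusted over the list alone). On average cell cycle genes changed by −0.86 ± 0.16 (adjusted p = 3.09e-05, and adjusted p = 0.195 with an estimated correlation) and by −1.22 to −0.43 within slides. Nusap1, a protein of the spindle, was 7.01-fold lower. Of 31 DNA repair genes, 1 rose and 10 fell (1 and 10 adjusted over the list alone). On average DNA repair genes changed by −0.48 ± 0.13 (adjusted p = 0.017, and adjusted p = 0.459 with an estimated correlation) and by −0.75 to −0.12 within slides. Of 29 ribosomal protein genes, 14 fell (18 adjusted over the list alone). On average ribosomal protein genes changed by −0.44 ± 0.15 (adjusted p = 7.8e-05, and adjusted p = 0.467 with an estimated correlation), which held on 3 of 5 slides (−0.88 to 0.23).

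The other lists were not called in WT. T cell markers averaged −0.46 ± 0.16 (adjusted p = 0.243), although Ccr7, a homing receptor of naive T cells, fell by 4.38 ± 0.28. Neutrophil markers averaged 0.42 ± 0.28 (0.0561), monocyte markers −0.43 ± 0.22 (0.114), inflammatory genes 0.00 ± 0.14 (0.915). P38 and JNK genes averaged −0.10 ± 0.10 (0.993), oxidative stress genes 0.32 ± 0.13 (0.51), oxidative phosphorylation genes −0.14 ± 0.11 (0.49), heat shock genes 0.12 ± 0.18 (0.759) and T cell activation genes 0.11 ± 0.09 (0.0705). Hepatocyte genes moved beside all of these groups. In WT 37 of 38 rose, by 6.65 ± 0.80 on average (exact permutation adjusted p = 0.0204), or 4.31 ± 0.75 without WT 7 Gy replicates 3 to 5. Their level went from −6.98 ± 0.17 (SD, n = 5) to −0.33 ± 2.14 (SD, n = 5), and hepatic acute phase genes rose by 4.33 ± 0.48 (exact permutation adjusted p = 0.0204). The hepatocyte and acute phase lists were chosen after seeing the data.

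**Figure D2:**
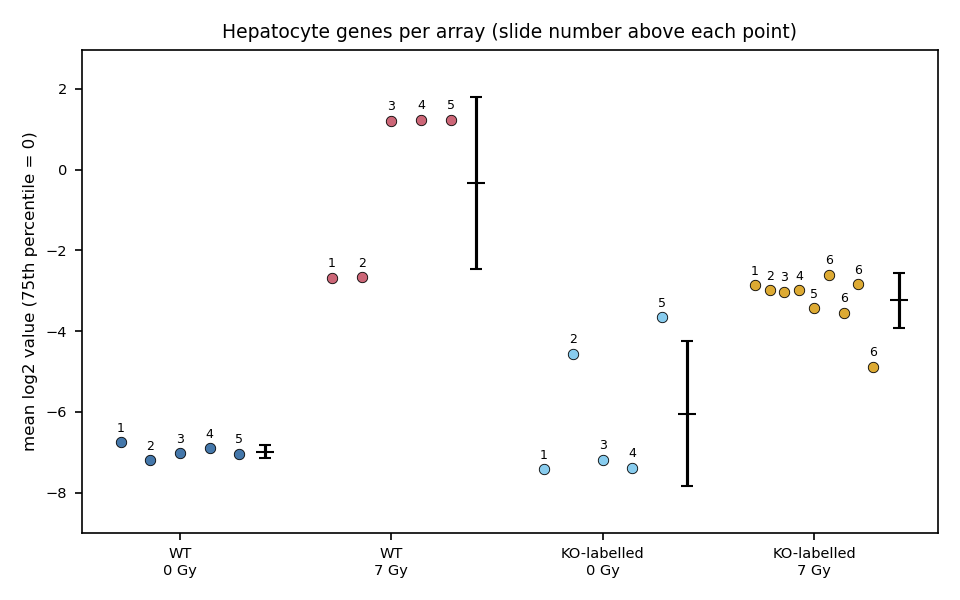
Mean log2 value of 38 hepatocyte genes per array, relative to the array's 75th percentile, by group, with the slide number above each point and the bar showing mean and SD of the arrays. WT arrays at 0 Gy lie near −6.98, WT arrays at 7 Gy between −2.68 and 1.24, and 2 KO-labelled arrays at 0 Gy, at −4.56 and −3.66, lie inside the range of the irradiated arrays. The lower end of that range is KO-labelled 7 Gy replicate 9, at −4.88, and the next irradiated array lies at −3.54, above both.

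In all, 1584 genes rose and 2141 fell in WT, of 15785 tested, and 4502 of all genes did not overlap between the groups (28.5%, where chance gives 0.794%). With slide as a block, 1853 rose and 2563 fell and all 11 called lists held, while neutrophil markers were called higher as well (0.0405). Averaging near-identical arrays left 135 and 308 genes, normexp background correction 377 and 372, and leaving out the noisy arrays 1739 and 2323. Without the 3 WT arrays highest in hepatocyte genes, 756 rose and 890 fell, and the DNA repair (adjusted p = 0.437) and ribosomal calls (0.456) ended. The DNA repair call also ended with near-identical arrays averaged (0.0766), the biodosimetry call with the authors' value table (0.0989) and the ribosomal call with quantile normalization (0.0663) and the exact permutation (0.104). Keeping only probes above background on all arrays ended the DNA repair (0.113) and biodosimetry calls (0.144). Without the 3 arrays, relative to the other genes, cell cycle genes went from −0.86 to −0.49 and erythroid markers from −1.45 to −0.91, and the uncalled neutrophil markers turned to −0.39. With an estimated correlation, the calls of p53 targets, B cell markers and interferon response genes held in WT, that of interferon response genes held between labels at 0 Gy, and all other list calls in any comparison were lost.

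The same comparison in KO-labelled arrays, 9 at 7 Gy against n = 4 at 0 Gy, gives the response under the other genotype label. Cdkn1a rose by 4.97 ± 0.36 (adjusted p = 7.88e-10), Phlda3 by 3.17 ± 0.16 (9.02-fold, 2.61e-11) and Gdf15, a stress cytokine, by 4.98 ± 0.59 (7.88e-07). B cell genes fell: Tnfrsf13c, the receptor for the survival factor BAFF, by 5.97 ± 0.49 (4.16e-09) and Ms4a1, which encodes CD20, fell by 5.62 ± 0.66 (5.96e-07). Gp1bb, part of the platelet receptor for von Willebrand factor, rose by 2.27 ± 0.26 (4.81-fold, 5.31e-07). Saa2 rose by 5.69 ± 0.71 (1.37e-06). Cdkn1a was well above background on 3 and Gdf15 and Saa2 on 1 of the KO-labelled arrays at 0 Gy, and Tnfrsf13c on 2 and Ms4a1 on 6 of those at 7 Gy, so the size of these changes is uncertain. Of the genes of hepatocytes, 26 of 38 rose, by 2.46 ± 0.76 on average (exact permutation adjusted p = 0.0204). Their level went from −5.70 ± 1.87 (SD, n = 4) to −3.24 ± 0.68 (SD, n = 9).

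Of 33 p53 targets, 20 rose and 5 fell (21 and 5 adjusted over the list alone). On average p53 targets changed by 1.08 ± 0.13 (2.11-fold, adjusted p = 1.84e-09, and adjusted p = 0.111 with an estimated correlation) and by 0.75 to 1.26 within slides. Ccng1 rose by 1.75 ± 0.19. Mdm2 rose by 0.46 ± 0.18 (adjusted p = 0.041), a call that ended with normexp correction (0.189), near-identical arrays averaged (0.185), without the noisy arrays (0.061) and without single arrays (0.055 to 0.11). Trp53 (0.000423) and Myc (0.0125) were called lower, but were well above background on only 4 and 5 of 9 KO-labelled arrays at 7 Gy, so no size is given, and both turned with normexp correction. The Myc call also ended with near-identical arrays averaged (0.0588) and without KO-labelled 0 Gy replicate 2 (0.0577) or 5. Of 22 platelet markers, 20 rose (22 adjusted over the list alone). On average platelet markers changed by 1.63 ± 0.17 (3.09-fold, adjusted p = 7.6e-18, and adjusted p = 0.111 with an estimated correlation) and by 0.93 to 2.10 within slides. The integrin Itgb3 rose by 2.08 ± 0.23. Of 30 interferon response genes, 15 rose (15 adjusted over the list alone). On average interferon response genes changed by 0.73 ± 0.12 (adjusted p = 4.12e-07, and adjusted p = 0.111 with an estimated correlation) and by 0.36 to 0.96 within slides. Ifit3 rose by 2.21 ± 0.29. Of 22 B cell markers, 22 fell (22 adjusted over the list alone). On average B cell markers changed by −4.36 ± 0.25 (20.5-fold lower, adjusted p = 8.91e-15, and adjusted p = 0.0504 with an estimated correlation) and by −4.88 to −3.33 within slides. Of 10 MHC class II genes, 10 fell (10 adjusted over the list alone). On average MHC class II genes changed by −3.30 ± 0.25 (9.87-fold lower, adjusted p = 6.49e-07, and adjusted p = 0.17 with an estimated correlation) and by −3.49 to −2.70 within slides. H2-Oa, a partner of H2-Ob, fell by 4.50 ± 0.37, with 5 of 9 arrays at 7 Gy well above background. Of 25 T cell markers, 1 rose and 17 fell (1 and 18 adjusted over the list alone). On average T cell markers changed by −1.10 ± 0.15 (2.14-fold lower, adjusted p = 0.000689, and adjusted p = 0.459 with an estimated correlation) and by −1.25 to −0.95 within slides. Ccr7 fell by 4.93 ± 0.27.

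Of 31 DNA repair genes, 1 rose and 23 fell (1 and 24 adjusted over the list alone). On average DNA repair genes changed by −1.16 ± 0.13 (2.23-fold lower, adjusted p = 0.000289, and adjusted p = 0.265 with an estimated correlation) and by −1.41 to −1.06 within slides. Pold1, a subunit of a replicative DNA polymerase, fell by 2.34 ± 0.24, with 6 of 9 arrays at 7 Gy well above background, a call that normexp correction ended (adjusted p = 0.242). Of 17 inflammatory genes, 10 fell (10 adjusted over the list alone). On average inflammatory genes changed by −0.84 ± 0.14 (adjusted p = 0.0318, and adjusted p = 0.382 with an estimated correlation) and by −1.33 to −0.57 within slides. The cytokine Il1b fell by 2.38 ± 0.41. The inflammatory call ended without KO-labelled 0 Gy replicate 5 (adjusted p = 0.0604) and with the authors' value table (0.128). Keeping only probes above background on all arrays ended the calls of B cell markers (0.134), DNA repair genes (0.156) and inflammatory genes (0.0611). Lists not called averaged 0.04 (adjusted p = 0.271) for biodosimetry genes, −0.60 (0.145) for cell cycle genes, −0.65 (0.289) for NK markers and −0.58 (0.51) for neutrophil markers. Monocyte markers averaged −0.51 (0.625), p38 and JNK genes −0.37 (0.699), oxidative stress genes 0.27 (0.114) and ribosomal genes −0.29 (0.315). Oxidative phosphorylation genes averaged −0.41 (0.231), heat shock genes −0.15 (0.678) and T cell activation genes −0.71 (0.849). Erythroid markers averaged −0.43 while the test leaned to higher values (0.914).

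In all, 1951 genes rose and 5454 fell. Of all genes, 3871 did not overlap between the groups (24.5%, where chance gives 0.28% if arrays are independent). The median change of all genes was −0.26 and depended on the scaling, which moved it by 0.34 with median scaling, 0.19 with quantile normalization and 0.53 with the authors' value table. Relative to the other genes, p53 targets changed by 1.32, platelet markers by 1.87, interferon genes by 0.97, B cell markers by −4.13, T cell markers by −0.86 and DNA repair genes by −0.92. The share of calls that rose was 26.3%, and 48.3% with median scaling, 39.3% with quantile normalization and 48% with the authors' value table. With slide as a block, 3514 rose and 5984 fell and all 8 called lists held. Averaging near-identical arrays left 1050 and 3424, normexp correction 806 and 576, and leaving out the noisy arrays 2135 and 5254.

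To ask whether the genotype label changes the response to 7 Gy, that of KO-labelled arrays was set against that of WT arrays. The difference is that between labels at 7 Gy minus that at 0 Gy. Ifit3 and Oasl1, which interferon induces, rose less in KO-labelled arrays: the difference of the responses was −3.39 ± 0.42 for Ifit3 (adjusted p = 0.000219, n = 9 and 4 against 5 and 5) and −2.94 ± 0.45 for Oasl1 (7.69-fold lower, 0.000749). Klra7, a receptor of killer cells, differed by −1.89 ± 0.36 (3.71-fold lower, 0.00263), as did Cd3g, a chain of the T cell receptor complex, at −1.50 ± 0.30 (2.82-fold lower, 0.00371). The response of Cnn1, a calponin, was 6.4-fold higher (2.68 ± 0.34, 0.000221), mostly because Cnn1 was lower in KO-labelled arrays at 0 Gy. That of the cyclin Ccna2 was 4.11-fold higher (2.04 ± 0.39, 0.00261). Of the genes followed in every comparison, Phlda3 rose more in KO-labelled arrays (0.95 ± 0.24, 0.012) and Gadd45a fell less (1.36 ± 0.27, 0.00377). Cdkn1a differed by 1.50 ± 0.52 without passing the test (0.0539), nor did Mdm2 (−0.61 ± 0.26; 0.109), Trp53 (−0.53 ± 0.38; 0.357) or Myc (−0.84 ± 0.68; 0.423; −0.25 without WT 0 Gy replicate 1).

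Of 19 NK and cytotoxic markers, 14 had a lower response (18 adjusted over the list alone). On average NK and cytotoxic markers differed by −1.49 ± 0.20 (adjusted p = 9.24e-10, and adjusted p = 0.111 with an estimated correlation) and by −1.77 to −1.09 within slides. Of 30 interferon response genes, 14 had a lower response (16 adjusted over the list alone). On average interferon response genes differed by −1.32 ± 0.17 (adjusted p = 4.74e-08, and adjusted p = 0.0949 with an estimated correlation) and by −1.80 to −0.73 within slides. Of 25 T cell markers, 0 had a higher response and 11 had a lower response (1 and 13 adjusted over the list alone). On average T cell markers differed by −0.64 ± 0.22 (adjusted p = 0.00284, and adjusted p = 0.502 with an estimated correlation) and by −0.89 to −0.31 within slides. Of 18 T cell activation genes, 6 had a lower response (9 adjusted over the list alone). On average T cell activation genes differed by −0.82 ± 0.12 (adjusted p = 0.0234, and adjusted p = 0.171 with an estimated correlation) and by −0.96 to −0.46 within slides. Of 31 DNA repair genes, 5 had a lower response (9 adjusted over the list alone). On average DNA repair genes differed by −0.68 ± 0.18 (adjusted p = 0.0182, and adjusted p = 0.459 with an estimated correlation) and by −1.16 to −0.40 within slides. Of 17 inflammatory genes, 4 had a lower response (6 adjusted over the list alone). On average inflammatory genes differed by −0.84 ± 0.20 (adjusted p = 0.00751, and adjusted p = 0.265 with an estimated correlation) and by −1.15 to −0.61 within slides. Tnfaip3, a brake on NF-kB, differed by −1.46 ± 0.25. Of 24 neutrophil markers, 0 had a higher response and 5 had a lower response (1 and 9 adjusted over the list alone). On average neutrophil markers differed by −1.0 ± 0.39 (adjusted p = 0.03, and adjusted p = 0.698 with an estimated correlation), which held on 4 of 5 slides (−2.55 to 0.34). Ly6g, a surface marker of neutrophils, differed by −1.93 ± 0.27.

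Of 30 erythroid markers, 12 had a higher response and 0 had a lower response (15 and 1 adjusted over the list alone). On average erythroid markers differed by 1.03 ± 0.30 (adjusted p = 3.08e-11, and adjusted p = 0.171 with an estimated correlation) and by 0.55 to 1.41 within slides. Of 22 platelet markers, 7 had a higher response (18 adjusted over the list alone). On average platelet markers differed by 0.85 ± 0.25 (adjusted p = 9.72e-11, and adjusted p = 0.23 with an estimated correlation) and by 0.11 to 1.32 within slides. Slc25a37, the iron importer of mitochondria, differed by 2.14 ± 0.55 (4.42-fold, adjusted p = 0.0137). Of 23 oxidative stress genes, 5 had a higher response and 2 had a lower response (5 and 2 adjusted over the list alone). On average oxidative stress genes differed by −0.05 ± 0.18 (adjusted p = 0.0455, and adjusted p = 0.401 with an estimated correlation), which held on 3 of 5 slides (−0.37 to 0.37). The median of oxidative stress genes was 0.31 and the test called them higher, opposite in sign to the mean, which was 0.28 with median scaling and −0.05 with quantile normalization. Of 29 ribosomal protein genes, 1 had a higher response (0 adjusted over the list alone). On average ribosomal protein genes differed by 0.16 ± 0.21 (adjusted p = 0.0498, and adjusted p = 0.767 with an estimated correlation), which held on 4 of 5 slides (−0.46 to 0.68). Limma called 0 of the ribosomal genes over the list alone, and their mean was −0.36 with quantile normalization. Not called were p53 targets at −0.42 (adjusted p = 0.334), biodosimetry genes at −0.41 (0.2), cell cycle genes at 0.26 (0.0501) and B cell markers at −0.41 (0.678). Monocyte markers averaged −0.08 (0.5), p38 and JNK genes −0.28 (0.696), oxidative phosphorylation genes −0.27 (0.471) and heat shock genes −0.28 (0.471), and MHC class II genes averaged −0.16 while the test leaned to higher values (0.699). Hepatocyte genes had a lower response beside these groups, by −4.19 ± 1.10 on average, with 25 of 38 called, but by −1.85 ± 0.93 with 0 called without WT 7 Gy replicates 3 to 5, and KO-labelled 0 Gy replicates 2 and 5 add to the difference. Mup17, a major urinary protein, was among the largest at −7.34 ± 1.58, uncertain in size because all WT arrays at 0 Gy were near background.

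In all, 504 genes had a higher and 1874 a lower response in KO-labelled arrays. Of those lower, 1197 fell in KO-labelled arrays alone and 311 rose in WT alone. Of those higher, 202 rose in KO-labelled arrays alone and 127 fell in WT alone. With near-identical arrays averaged, limma called 0 higher and 0 lower (1467 at an unadjusted p under 0.05), and with normexp correction also 0 and 0 (914), so that none of the gene calls of this comparison holds under either. Blocking on slide gave 1740 and 3386, without the noisy arrays 229 and 1279, and without the 3 WT arrays highest in hepatocyte genes 118 and 845. That last fit ended the calls of Slc25a37 (adjusted p = 0.223, and 0.0513 without the noisy arrays), Mup17 (0.0966), Phlda3 (0.134, and 0.0729 with the authors' value table), inflammatory genes (0.0566), neutrophil markers (0.731, with the mean relative to other genes turning to 0.05) and ribosomal genes (0.218). In it, relative to the other genes, erythroid markers went from 1.26 to 0.72, DNA repair genes from −0.45 to −0.74, T cell markers from −0.41 to −0.79 and oxidative stress genes from 0.18 to 0.59. It also called B cell markers (−0.80; adjusted p = 0.0203) and biodosimetry genes (−0.38; 0.0282) lower, and without the noisy arrays cell cycle genes were called higher (0.0383). The fit without the 3 WT arrays rests on WT 7 Gy replicates 1 and 2, a near-identical set that may share an RNA. Leaving out KO-labelled 0 Gy replicate 2 left 315 higher, replicate 5 left 264 higher and 1091 lower, and leaving out KO-labelled 7 Gy replicate 9 gave 786 higher.

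The median difference of all genes was −0.25 and moved by 0.33 with median scaling, 0.21 with quantile normalization and 0.29 with the authors' value table. The share of called genes with a higher response was 21.2%, 42.1% with quantile normalization and 49.7% with the authors' value table, and the balance turned with median scaling (61.7%). Relative to the other genes, NK markers differed by −1.25, interferon genes by −1.09, T cell markers by −0.41, T cell activation genes by −0.58, DNA repair genes by −0.45, inflammatory genes by −0.60, neutrophil markers by −0.77, erythroid markers by 1.26, platelet markers by 1.08, oxidative stress genes by 0.18 and ribosomal genes by 0.39. With slide as a block, the calls of oxidative stress genes (adjusted p = 0.223), ribosomal genes (0.0873) and T cell activation genes (0.124) ended, and averaging near-identical arrays ended those of neutrophil markers (0.116) and ribosomal genes (0.517). Keeping only probes above background on all arrays ended those of DNA repair genes (0.536), T cell activation genes (0.191), neutrophil markers (0.112), oxidative stress genes (0.176) and ribosomal genes (0.232). The last 2 also ended with fry (0.281 and 0.761), the authors' value table (0.177 and 0.104) and no filter (0.148 and 0.151). The T cell activation call ended with KO-labelled 7 Gy replicates 1 to 5 alone (0.0973), and the neutrophil (0.204) and ribosomal calls (0.113) with replicates 6 to 9 alone. The call of DNA repair genes ended without WT 7 Gy replicate 1 (0.0526) or 2 (0.0599), and that of T cell activation genes without KO-labelled 7 Gy replicate 9 (0.065). The neutrophil call ended in each of 8 leave-outs (KO-labelled 0 Gy replicates 3 and 5, KO-labelled 7 Gy replicates 5, 7 and 9, and WT 7 Gy replicates 3, 4 and 5; adjusted p = 0.0562 to 0.0816), the oxidative stress call in 9 (0.052 to 0.157) and the ribosomal call in 13 (0.0536 to 0.241).

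At 0 Gy, KO-labelled arrays (n = 4) were compared with WT arrays (n = 5) for differences before exposure. Selenbp1, a selenium-binding protein, was higher by 2.45 ± 0.31 (5.46-fold, adjusted p = 0.000447), Tspo2, a cholesterol-binding protein of red cell precursors, by 2.17 ± 0.28 (4.5-fold, 0.000608), Asns, the asparagine synthetase, by 1.98 ± 0.31 (3.95-fold, 0.0048) and Ifi47, a GTPase induced by interferon, 2.78-fold (0.00219). Cnn1 was lower by a log2 difference of −2.35 ± 0.26 (5.11-fold lower, 0.000113). Of 30 interferon response genes, 3 were higher (14 adjusted over the list alone). On average interferon response genes differed by 0.75 ± 0.13 (adjusted p = 4.55e-13, and adjusted p = 0.0257 with an estimated correlation) and by 0.46 to 1.10 within slides.

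Of 17 heat shock genes, 2 were higher (5 adjusted over the list alone). On average heat shock genes differed by 0.49 ± 0.20 (adjusted p = 5.53e-07, and adjusted p = 0.265 with an estimated correlation) and by 0.17 to 0.98 within slides. Of 19 NK and cytotoxic markers, 0 were higher (1 adjusted over the list alone). On average NK and cytotoxic markers differed by 0.56 ± 0.15 (adjusted p = 3.32e-07, and adjusted p = 0.17 with an estimated correlation) and by 0.37 to 0.87 within slides. Of 22 B cell markers, 0 were higher (0 adjusted over the list alone). On average B cell markers differed by 0.56 ± 0.28 (adjusted p = 0.00186, and adjusted p = 0.401 with an estimated correlation) and by 0.33 to 0.82 within slides. Of 31 DNA repair genes, 0 were higher (0 adjusted over the list alone). On average DNA repair genes differed by 0.35 ± 0.14 (adjusted p = 0.00271, and adjusted p = 0.35 with an estimated correlation) and by 0.16 to 0.43 within slides. Of 24 cell cycle genes, 0 were higher (0 adjusted over the list alone). On average cell cycle genes differed by 0.30 ± 0.17 (adjusted p = 0.00619, and adjusted p = 0.401 with an estimated correlation) and by 0.11 to 0.37 within slides. For these last 3 lists limma called 0 members over all genes and over the list alone. The cell cycle call ended without KO-labelled 0 Gy replicate 5 (adjusted p = 0.0604). Of 24 neutrophil markers, 0 were higher and 0 were lower (1 and 9 adjusted over the list alone). On average neutrophil markers differed by −0.62 ± 0.30 (adjusted p = 1.03e-06, and adjusted p = 0.275 with an estimated correlation) and by −1.29 to −0.13 within slides. Of 22 platelet markers, 0 were lower (3 adjusted over the list alone). On average platelet markers differed by −0.43 ± 0.19 (adjusted p = 1.75e-09, and adjusted p = 0.265 with an estimated correlation), which held on 4 of 5 slides (−0.92 to 0.15). Keeping only probes above background on all arrays ended the calls of B cell markers (0.668) and DNA repair genes (0.195). Fry ended those of B cell markers (0.0846), cell cycle genes (0.0624), neutrophil markers (0.132) and platelet markers (0.0786), and the exact permutation that of platelet markers (0.0518). Hepatocyte genes averaged 1.28 ± 0.84 higher, with 0 of 38 called (exact permutation adjusted p = 0.476). The value was 0.60 without KO-labelled 0 Gy replicate 5 and 1.77 without replicate 3. The other lists were not called at 0 Gy (adjusted p = 0.0627 to 0.662). Biodosimetry (0.0294) and inflammatory genes (0.0307) were called higher with near-identical arrays averaged, and T cell markers without the noisy arrays (0.00307). Ribosomal genes were called higher with quantile normalization (0.28 relative to the other genes, adjusted p = 2.15e-05). The median difference of all genes was 0.09, and median scaling moved it by −0.10 and quantile normalization by −0.11. Relative to the other genes, interferon genes differed by 0.69, NK markers by 0.49, B cell markers by 0.49, heat shock genes by 0.43, DNA repair genes by 0.28, cell cycle genes by 0.23, neutrophil markers by −0.69 and platelet markers by −0.50. Heat shock genes went to 0.19 without KO-labelled 0 Gy replicate 5, and neutrophil markers to −0.42 and platelet markers to −0.29 without replicate 2.

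In all, 33 genes were higher and 13 lower, with 1472 at an unadjusted p under 0.05. Of all genes, 1679 did not overlap between the groups (10.6%, where chance gives 1.59% if arrays are independent, and more if near-identical arrays share an RNA). Averaging near-identical arrays left limma with 0 and 0 (496 at an unadjusted p under 0.05), and normexp correction left 1 higher, Tspo2, and 0 lower (306). Blocking on slide with KO-labelled 0 Gy replicates 1 and 4 kept separate gave 68 higher and 29 lower and all 8 list calls held. Keeping them separate without a block gave 60 and 19. Leaving out the noisy arrays gave 30 and 7. The share higher of 71.7% moved to 52.6% with median scaling and 63.6% with quantile normalization. The count higher was 13 without KO-labelled 0 Gy replicate 3, 11 without replicate 5, 50 without KO-labelled 7 Gy replicate 9, and 20, 14, 15 and 13 without WT 0 Gy replicates 1, 2, 3 and 4. The count lower was 1 without KO-labelled 0 Gy replicate 5, 23 without KO-labelled 7 Gy replicate 6, and 8, 2, 2, 2 and 7 without WT 0 Gy replicates 1 to 5.

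At 7 Gy, KO-labelled arrays (n = 9) were compared with WT arrays (n = 5) for differences that remain after exposure. S100a8, a calcium-binding protein of granulocytes, was lower in KO-labelled arrays by a log2 difference of −3.02 ± 0.33 (8.09-fold lower, adjusted p = 3.41e-06), Mmp9, a matrix protease, by −3.26 ± 0.40 (9.56-fold lower, 9.33e-06) and Il1b by −3.11 ± 0.38 (8.61-fold lower, 9.33e-06). Ifit3 was 4.58-fold lower (−2.20 ± 0.27; 9.33e-06) and Clic5, a chloride channel protein, at least 10.9-fold lower (4.59e-08), its KO-labelled arrays being at background. Tspo2 was 5.15-fold higher (2.36 ± 0.23; 1.74e-06), Ccna2 4.47-fold higher (2.16 ± 0.25; 5.03e-06) and Cul4a, a scaffold of ubiquitin ligases, 3.6-fold higher (1.85 ± 0.16; 3.56e-07).

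Of 24 neutrophil markers, 1 were higher and 18 were lower (1 and 18 adjusted over the list alone). On average neutrophil markers differed by −1.62 ± 0.25 (3.08-fold lower, adjusted p = 9.49e-08, and adjusted p = 0.253 with an estimated correlation) and by −2.67 to −0.88 within slides. Of 19 NK and cytotoxic markers, 15 were lower (15 adjusted over the list alone). On average NK and cytotoxic markers differed by −0.93 ± 0.13 (adjusted p = 3.15e-07, and adjusted p = 0.17 with an estimated correlation) and by −1.38 to −0.67 within slides. Klrd1, a receptor of NK cells, differed by −1.44 ± 0.23. Of 30 interferon response genes, 1 were higher and 14 were lower (1 and 16 adjusted over the list alone). On average interferon response genes differed by −0.57 ± 0.11 (adjusted p = 0.00426, and adjusted p = 0.349 with an estimated correlation) and by −1.04 to −0.20 within slides. Of 25 T cell markers, 11 were lower (12 adjusted over the list alone). On average T cell markers differed by −0.46 ± 0.14 (adjusted p = 0.00401, and adjusted p = 0.512 with an estimated correlation) and by −0.82 to −0.05 within slides. Cd3g differed by −1.22 ± 0.19. Of 18 T cell activation genes, 8 were lower (9 adjusted over the list alone). On average T cell activation genes differed by −0.57 ± 0.08 (adjusted p = 0.03, and adjusted p = 0.18 with an estimated correlation) and by −0.63 to −0.35 within slides. Bcl6, a repressor that shapes follicular helper T cells, differed by −1.92 ± 0.27 and Fasl, a death ligand, by −1.27 ± 0.20. Of 17 inflammatory genes, 6 were lower (9 adjusted over the list alone). On average inflammatory genes differed by −0.59 ± 0.13 (adjusted p = 0.03, and adjusted p = 0.382 with an estimated correlation) and by −0.81 to −0.31 within slides.

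Of 30 erythroid markers, 19 were higher (20 adjusted over the list alone). On average erythroid markers differed by 1.04 ± 0.19 (2.06-fold, adjusted p = 6.25e-15, and adjusted p = 0.111 with an estimated correlation) and by 0.83 to 1.66 within slides. Of 24 cell cycle genes, 8 were higher and 0 were lower (8 and 1 adjusted over the list alone). On average cell cycle genes differed by 0.56 ± 0.14 (adjusted p = 1.2e-05, and adjusted p = 0.175 with an estimated correlation) and by 0.21 to 1.07 within slides. Mki67, a marker of dividing cells, differed by 1.72 ± 0.24. Of 22 platelet markers, 4 were higher (3 adjusted over the list alone). On average platelet markers differed by 0.41 ± 0.16 (adjusted p = 1.5e-06, and adjusted p = 0.382 with an estimated correlation), which held on 4 of 5 slides (−0.07 to 0.50). Of 17 heat shock genes, 3 were higher and 1 were lower (5 and 2 adjusted over the list alone). On average heat shock genes differed by 0.22 ± 0.16 (adjusted p = 0.0349, and adjusted p = 0.711 with an estimated correlation), which held on 4 of 5 slides (−0.05 to 0.42). Hepatocyte genes were lower beside these groups, by −2.91 ± 0.70 on average, with 31 of 38 called (exact permutation adjusted p = 0.00899), but by −0.57 ± 0.71 with 0 called without WT 7 Gy replicates 3 to 5. Cyp2a4, a cytochrome of the liver, was lower by a log2 difference of −4.83 ± 0.85 (adjusted p = 0.000335), with 4 of 9 KO-labelled arrays above background. The median difference of all genes was −0.11 and moved by 0.22 with median scaling and 0.28 with the authors' value table. Relative to the other genes, neutrophil markers differed by −1.46, NK markers by −0.76, interferon genes by −0.40, T cell markers by −0.30, T cell activation genes by −0.41, inflammatory genes by −0.43, erythroid markers by 1.21, cell cycle genes by 0.72, platelet markers by 0.58 and heat shock genes by 0.38.

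In all, 723 genes were higher and 2808 lower, and 954 of all genes did not overlap between the groups (6.04%, where chance gives 0.0999%). Averaging near-identical arrays left limma with 0 and 0 (1621 at an unadjusted p under 0.05), so that none of the gene calls of this comparison holds under it, and normexp correction left 99 and 130. Normexp ended the calls of Mmp9 (adjusted p = 0.0745), Clic5 (0.364), Ccna2 (0.835), Cul4a (0.185), Cd3g (0.178), Bcl6 (0.134) and Cyp2a4 (0.0686). It also ended those of Klrd1, Fasl and Mki67 (0.934 each), of which Mki67 was lost with the authors' value table too (0.299). Blocking on slide gave 2045 higher and 3943 lower, and leaving out the noisy arrays 751 and 2925. The share higher of 20.5% moved to 49.7% with median scaling and 33.9% with quantile normalization. Without the 3 WT arrays highest in hepatocyte genes, 125 were higher and 995 lower, and the calls of interferon genes (adjusted p = 0.403), inflammatory genes (0.189) and Cyp2a4 (0.2) ended. In it, relative to the other genes, neutrophil markers went from −1.46 to −0.64, erythroid markers from 1.21 to 0.66, cell cycle genes from 0.72 to 0.36, NK markers from −0.76 to −1.18 and T cell markers from −0.30 to −0.67. It also called DNA repair genes (−0.46; adjusted p = 0.00119) and ribosomal genes (−0.15; 0.00627) lower and oxidative stress genes higher (0.49; 2.07e-05), of the 10 lists not called with all arrays (0.1 to 0.849). That fit rests on WT 7 Gy replicates 1 and 2, a near-identical set that may share an RNA. With slide as a block, the calls of T cell markers (adjusted p = 0.05), heat shock genes (0.143) and T cell activation genes (0.168) ended. The inflammatory call also ended without WT 7 Gy replicate 5 (0.0558), that of T cell activation genes without KO-labelled 7 Gy replicate 7 (0.0529) or 9 (0.096), and that of heat shock genes without KO-labelled 7 Gy replicate 5, 7 or 9 or WT 7 Gy replicate 1 or 2 (0.0651 to 0.118). Keeping only probes above background on all arrays ended the calls of T cell activation genes (0.167), inflammatory genes (0.113) and heat shock genes (0.204). The T cell activation call also ended with quantile normalization (0.0566) and KO-labelled 7 Gy replicates 1 to 5 alone (0.134), and the inflammatory call with the authors' value table (0.104) and replicates 6 to 9 alone (0.0506). The heat shock call also ended with fry (0.403), the exact permutation (0.298), the authors' value table (0.187), replicates 1 to 5 alone (0.125) and no filter (0.156), and the platelet call with the exact permutation (0.0518).

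**Figure D3:**
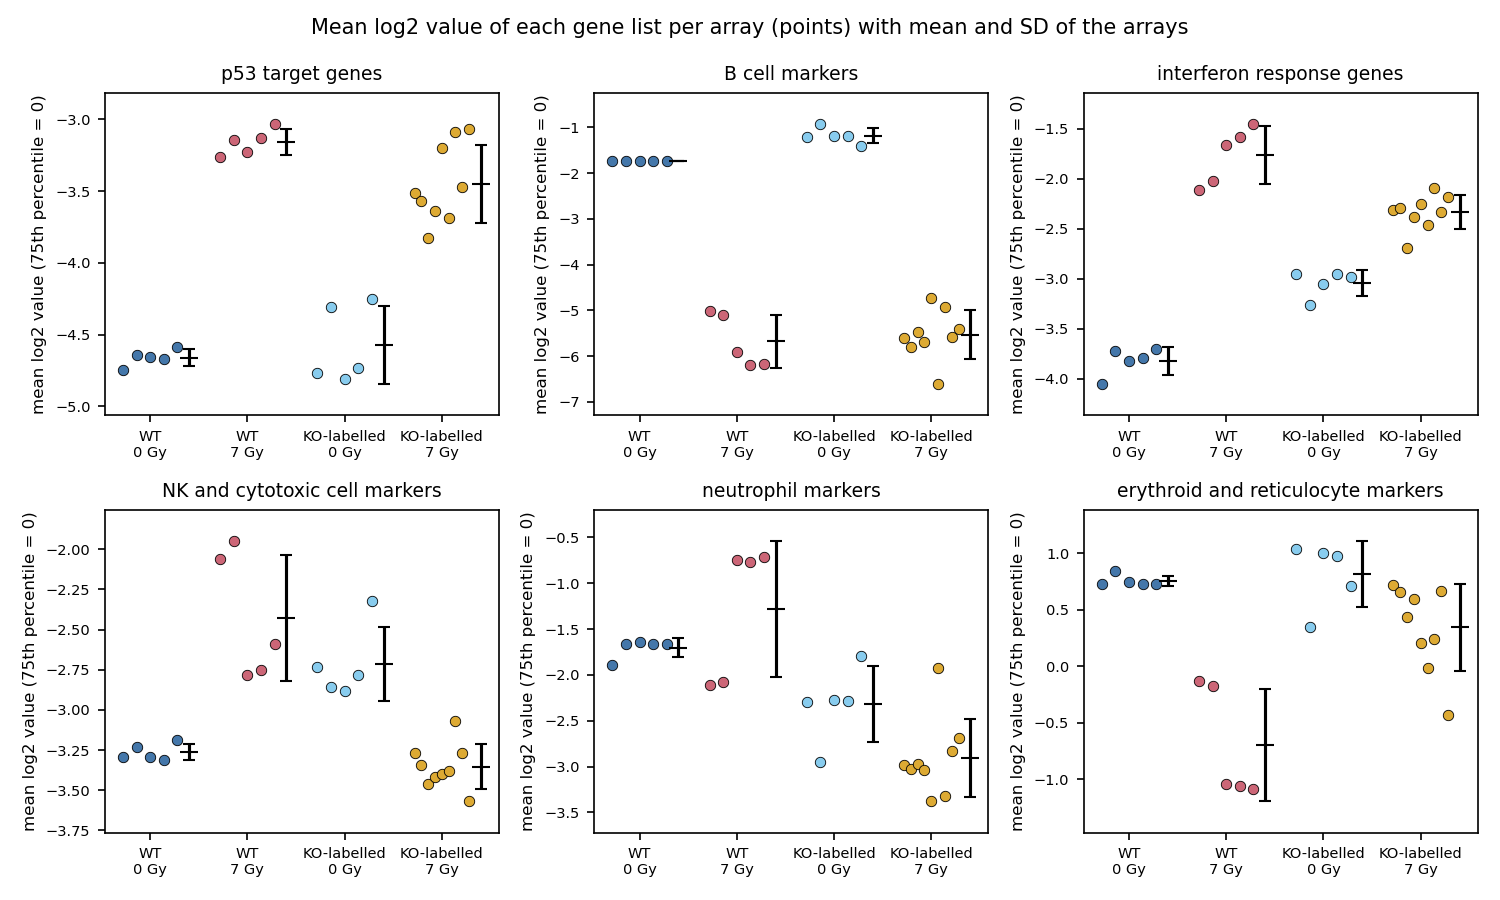
Mean log2 value of 6 gene lists per array, relative to the array's 75th percentile, by group, with each point an array and the bar the mean and SD of the arrays. B cell markers lie between −6.61 and −4.74 in the KO-labelled arrays at 7 Gy and near −1.73 in the WT arrays at 0 Gy, and NK markers are lower in every KO-labelled array at 7 Gy than in any WT array at 7 Gy.

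The responses under both labels were also compared across genes, which are not independent replicates. Their log2 changes correlated with Pearson's r = 0.62 (jackknife SE over the arrays 0.122) and Spearman's rho = 0.54 across 15785 genes. Of the genes called in WT, 88.3% had the same sign in KO-labelled arrays, and of those called in KO-labelled arrays, 83% had the same sign in WT. Both called 744 genes higher, where independence gives 196, and 1663 lower, where it gives 740, and 90 in opposite directions. Cdkn1a, Phlda3, Ccng1, Aen and Bax rose under both labels, and Fcmr, Vpreb3 and Ccr7 fell under both.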

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

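The tests of explanations in this part were chosen only after the results were seen, except the counts of other splits of the samples.

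The responses to 7 Gy differed between the genotype labels for 504 genes that were higher and 1874 that were lower in KO-labelled arrays. By list, the difference was −0.68 ± 0.18 (SE; adjusted p = 0.0182) for DNA repair genes, −0.64 ± 0.22 (0.00284) for T cell markers, −1.49 ± 0.20 (9.24e-10) for NK markers and −1.0 ± 0.39 (0.03) for neutrophil markers. It was 1.03 ± 0.30 (3.08e-11) for erythroid markers, 0.85 ± 0.25 (9.72e-11) for platelet markers, −1.32 ± 0.17 (4.74e-08) for interferon response genes and −0.84 ± 0.20 (0.00751) for inflammatory genes. Oxidative stress genes differed by −0.05 ± 0.18 on average while the test called them higher (0.0455), ribosomal protein genes by 0.16 ± 0.21 (0.0498) and T cell activation genes by −0.82 ± 0.12 (0.0234). Among the genes followed throughout, Gadd45a differed by 1.36 ± 0.27 (0.00377) and Phlda3 by 0.95 ± 0.24 (0.012). With an estimated correlation none of these 11 list calls held (adjusted p = 0.0949 to 0.767).

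Of 100 splits of the arrays, 1, the real one, called as many genes in each comparison. This argues against chance if the arrays are independent samples. Whether they are is in doubt, since near-identical arrays may share an RNA. With near-identical arrays averaged, limma called 0 genes for the difference of the responses (1467 at an unadjusted p under 0.05), 0 at 0 Gy (496) and 0 at 7 Gy (1621), so chance stays open for these 3 if such arrays share an RNA. The real counts and the highest of the other splits were 3725 and 566 genes in WT, 7405 and 4786 in KO-labelled arrays, 2378 and 3 for the difference of the responses, 46 and 0 at 0 Gy, and 3531 and 1797 at 7 Gy.

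In 14 of 120 groups of values, 1 array lay far from the others of its group, where chance gives about 1 in 20 groups. WT 0 Gy replicate 1, an array with noisy repeat spots, was low for biodosimetry genes (−3.57, nearest other −3.29), neutrophil markers (−1.89, nearest −1.66), platelet markers (−0.03, nearest 0.20), Bax (−1.82, nearest −1.40) and Myc (−7.34, nearest −4.43). WT 0 Gy replicate 2 was high for erythroid markers (0.84, nearest 0.75), WT 7 Gy replicate 5 low for Cdkn1a (−2.17, nearest −1.74) and KO-labelled 0 Gy replicate 5 high for Mdm2 (−1.10, nearest −1.54). KO-labelled 7 Gy replicate 6 was high for neutrophil markers (−1.92, nearest −2.69) and low for monocyte markers (−3.31, nearest −2.47) and MHC class II genes (−5.03, nearest −3.70). KO-labelled 7 Gy replicate 9 was low for T cell activation genes (−4.19, nearest −3.96) and hepatocyte genes (−4.88, nearest −3.54), and replicate 3 low for Phlda3 (0.05, nearest 0.39).

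Hepatocyte genes rose with 7 Gy under both labels, and albumin went from −7.26 ± 0.19 (SD, n = 5) to 2.15 ± 2.48 (SD, n = 5) in WT. Acute phase genes switched on in blood cells are argued against, because the median change of the 33 hepatocyte genes outside the acute phase was 7.08 in WT. A slide or scan batch is argued against by the 0 Gy WT arrays on the slides of the 3 high arrays, which differed from the other 0 Gy WT arrays by −0.01. 7 Gy as the only source is argued against by KO-labelled 0 Gy replicate 5, which lay 3.32 above the 0 Gy WT mean (SD 0.17), with B cell markers at −1.40 where irradiated arrays reached at most −4.74. RNA of liver cells in the blood samples may be the source. The highest 0 Gy array correlated with the irradiated WT profile across hepatocyte genes at 0.96, against 0.41 to 0.73 for the other 0 Gy arrays. That array was picked for its level, and the others were lower in these genes, which by itself can lower a correlation. The correlation therefore does not tell liver cells from another source of these transcripts.

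Near-identical arrays formed 5 sets, and the SD of the log2 difference within a set was 0.097 to 0.231. This SD was estimated from the median absolute deviation of bright probes, so it leaves out dim probes and gives little weight to strong single differences. As the source of the sets, resemblance of arrays on one slide is argued against. The 6 pairs on slide 6 differed by an SD of 0.475 to 0.771, and all 5 sets span slides. Arrays of different groups with one replicate number correlated at 0.22 on average. One RNA on several arrays may account for the sets, with differences of 0.98 to 2.17 times the repeat-spot noise. Arrays of different groups came as close as 1.99 times (a pair with a noisy array) and an SD of 0.268. A shared RNA cannot be told apart from mice that differ little, as the files name no repeat arrays. If arrays of a set share an RNA, the counts of genes are too high, and the fit that averages each set is the one to read.

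Gadd45a of KO-labelled arrays differed from WT by −0.15 at 0 Gy, where a knockout leaves no full transcript. Between the 14 KO-labelled and 10 WT arrays 7 genes did not overlap, against at most 0 in 99 other assignments of single arrays, but 39 of 279 assignments that keep near-identical sets whole gave at least 7, so labels mixed up between arrays stay open. A probe outside the deleted part of the gene may account for the level, and this cannot be told apart from an intact gene, because the deleted part is not given in the sources used here. Genes taken to differ between labels at both doses, by a looser rule than the calls, were counted near Gadd45a. They were 1.8% of those within 20 Mb and 0.825% of the others without immunoglobulin kappa genes (Fisher's exact p = 0.117). With kappa genes the shares were 2.68% and 0.824% (Fisher's exact p = 0.00425). The others held 126 such genes, where only 46 were called at 0 Gy, so most of them are not called genes. DNA kept from the original stem cell strain stays open.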

How the results depend on the processing

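The alternatives chosen after seeing the data were the 75th percentile over all probes, KO-labelled 7 Gy replicates 6 to 9 alone, KO-labelled 0 Gy replicates 1 and 4 as separate arrays, near-identical arrays averaged, the fit without the 4 noisy arrays and the fit without WT 7 Gy replicates 3 to 5. Counts are given as higher and lower genes for WT, KO-labelled arrays, the difference of the responses, 0 Gy and 7 Gy, where they moved by over 1.5 times. Except where a construction is named, the cause was not tested. Under the alternatives chosen beforehand, other than leaving out arrays, 70 counts of genes stayed within 1.5 times and 78 did not, and 28 and 32 under those added. Of the values of called and uncalled lists, 1004 kept direction and side of the threshold, 102 became weaker, 69 stronger and 5 turned; of those of named genes, 5156, 610, 32 and 14 did. A trend with robust variances and the mean of a gene's probes moved no count of genes. Normexp background correction with an offset of 50 moved every count of genes, and the parts of the correction and the offset were not told apart.

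Normexp gave 377 and 372 in WT, 806 and 576 in KO-labelled arrays, 0 and 0 for the difference by limma (914 at an unadjusted p under 0.05), 1 and 0 at 0 Gy (306), and 99 and 130 at 7 Gy. Quantile normalization gave 633 lower for the difference, 21 higher at 0 Gy and 1711 lower at 7 Gy. Median scaling gave 3167 and 3394 in KO-labelled arrays, 907 and 563 for the difference, 10 higher at 0 Gy, and 1384 and 1401 at 7 Gy. The 75th percentile over all probes gave 3060 and 3491 in KO-labelled arrays, 887 and 581 for the difference, 10 higher at 0 Gy, and 1349 and 1456 at 7 Gy. The authors' value table gave 1230 lower in WT, 2721 lower in KO-labelled arrays, 223 and 226 for the difference, 12 and 2 at 0 Gy and 835 lower at 7 Gy, and it tests fewer genes (12856). No filter on dim probes gave 159 and 830 for the difference, 8 and 1 at 0 Gy and 474 higher at 7 Gy. Probes above background on all arrays, with fewer genes tested (6756), gave 789 and 1374 in WT, 1221 and 2642 in KO-labelled arrays, 1112 lower for the difference and 1399 lower at 7 Gy.

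The replicate block gave 3775 higher in KO-labelled arrays, 2180 and 4023 for the difference, 179 and 118 at 0 Gy, and 2399 and 4411 at 7 Gy. It ended the list calls of biodosimetry genes in WT (0.058), T cell activation (0.13), oxidative stress (0.2) and ribosomal genes (0.0838) for the difference, and T cell activation (0.168) and heat shock genes (0.152) at 7 Gy. It also brought 5 list values past the threshold that were not called without the block. Replicates 1 to 5 of one number share a slide, and no label names a shared animal; 21 of 30 pairs with one number correlated above 0.1 (−0.23 to 0.70), with a mean of 0.22 against −0.05 for other pairs, and 12 of 20 arrays correlated best with their own number. Slide as a block gave 3514 higher in KO-labelled arrays, 1740 and 3386 for the difference, 68 and 29 at 0 Gy and 2045 higher at 7 Gy. Scan date as a block gave 3123 higher in KO-labelled arrays, 1303 and 3360 for the difference, 79 and 41 at 0 Gy and 1595 higher at 7 Gy. Array weights gave 3944 and 4947 in WT, 3395 higher in KO-labelled arrays, 2588 and 4992 for the difference, 524 and 378 at 0 Gy, and 3672 and 5871 at 7 Gy. A change of at least 2-fold, a stricter rule by construction, gave 1038 and 1104 in WT, 1202 and 3227 in KO-labelled arrays, and 277 and 1247 at 7 Gy.

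KO-labelled 7 Gy replicates 1 to 5 alone gave 981 and 3243 for the difference, 65 and 24 at 0 Gy and 1327 higher at 7 Gy. Replicates 6 to 9 alone gave 246 and 998, 19 and 5, and 347 and 1365 in the same comparisons. Fitting the groups of a contrast alone gave 57 higher at 0 Gy, and the pair of KO-labelled 0 Gy arrays kept separate 60 higher. Near-identical arrays averaged, with fewer samples, gave 135 and 308 in WT, 1050 and 3424 in KO-labelled arrays, and by limma 0 and 0 for the difference (1467 at an unadjusted p under 0.05), 0 and 0 at 0 Gy (496) and 0 and 0 at 7 Gy (1621). Leaving out the 4 noisy arrays gave 229 higher for the difference and 7 lower at 0 Gy. Without WT 7 Gy replicates 3 to 5 the counts were 756 and 890 in WT, 118 and 845 for the difference, and 125 and 995 at 7 Gy.

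Leaving out each array gave 1237 to 1699 and 1690 to 2333 in WT, 1711 to 2025 and 4794 to 5800 in KO-labelled arrays, and 490 to 982 and 2163 to 3625 at 7 Gy. The difference had 264 to 786 higher and 1091 to 2779 lower. At 0 Gy, 11 to 50 were higher, as given above by array. Lower at 0 Gy were 1 to 23. The correlation of the responses was 0.54 to 0.68 and the Gadd45a difference at 0 Gy −0.24 to −0.08.

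Lists called were 11, 8, 11, 8 and 10 in the 5 comparisons. No filter gave 14 in KO-labelled arrays and 13 at 0 Gy, probes above background on all arrays 5 in KO-labelled arrays and 6 for the difference, the estimated correlation 3, 0, 0, 1 and 0, fry 15 in KO-labelled arrays and 5 at 0 Gy, and the exact permutation 15 in KO-labelled arrays. Differences of list levels between groups numbered 46. They were 29 with the authors' value table, 20 with replicates 6 to 9 alone, 0 with near-identical arrays averaged, 21 without WT 7 Gy replicates 3 to 5, and 33 to 47 leaving out each array. Averaging left 2 units in each WT group, 3 in KO-labelled arrays at 0 Gy and 6 at 7 Gy. With so few units the exact permutation cannot pass the threshold in any comparison with WT arrays, so the 0 decides nothing there. The other cuts to fewer arrays also raise the smallest p that it can give.

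Some values turned in sign, with lists given relative to the other genes. For the difference, oxidative stress genes turned to −0.03 with quantile normalization and −0.02 without a filter, ribosomal genes to −0.34 with quantile normalization and −0.03 without WT 7 Gy replicates 3 to 5, and neutrophil markers to 0.05 without those. Ribosomal genes turned to 0.28 at 0 Gy with quantile normalization and −0.15 at 7 Gy without WT 7 Gy replicates 3 to 5, oxidative phosphorylation genes to −0.23 at 7 Gy without a filter, and Gstm1 to 0.23 at 7 Gy without those replicates. Normexp turned Apex1 to 0.42, Cd8a to 0.07, Camp to 0.01, Nfkb2 to 0.05 and Hsf1 to 0.38 in WT. In KO-labelled arrays it turned Fanca to 0.14, Klrg1 to 0.04, Treml4 to 0.30, Birc3 to 0.11, Nfkb1 to 0.19, Fos to 0.22, Trp53 to 0.34 and Myc to 0.17. The authors' value table turned Nfatc2 to 0.42 for the difference.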

Other observations

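The genes and lists in this part were chosen after their values were seen. Npy, a neuropeptide, was either present or near background in KO-labelled arrays: its level ranged from −9.42 to 0.90 at 0 Gy and from −8.20 to 2.65 at 7 Gy, while all WT arrays lay between −9.44 and −7.35. The low KO-labelled arrays were replicate 5 at 0 Gy and replicates 6 and 9 at 7 Gy. Its probe starts at 49773743 on chromosome 6, the chromosome of Gadd45a. Tspo2 separated all arrays by label with a gap of 0.89, and its neighbour on chromosome 17, Unc5cl, was higher in KO-labelled arrays by 2.54 ± 0.48 (SE) at 0 Gy, where WT arrays were near background, and by 2.62 ± 0.40 at 7 Gy. Stfa1, a protease inhibitor of neutrophils on chromosome 16, differed by −1.69 ± 0.40 (SE) at 0 Gy without passing the test (adjusted p = 0.0793) and by −2.91 ± 0.33 at 7 Gy (5.03e-06), while its relative Stfa3 differed by −0.29 and 0.01.

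Targets of ATF4, a factor of the amino acid stress response that controls Asns, averaged 0.47 ± 0.14 higher in KO-labelled arrays at 0 Gy, with 2 of 16 called (exact permutation adjusted p = 0.0204). After 7 Gy they averaged −1.05 ± 0.12 in KO-labelled arrays, with 11 lower and 1 higher (exact permutation adjusted p = 0.00899), and averaged −0.15 ± 0.13 in WT (0.446). Between labels they differed by −0.42 ± 0.11 at 7 Gy, with 4 lower and 1 higher (exact permutation adjusted p = 0.0126; −0.18 ± 0.15 without WT 7 Gy replicates 3 to 5), and their responses by −0.90 ± 0.18. Eosinophil and basophil genes averaged 0.50 ± 0.16 higher in KO-labelled arrays at 0 Gy, with 0 of 8 called (exact permutation adjusted p = 0.0204). This rested on replicates 2 and 5, at −3.48 and −3.45, while the other KO-labelled arrays lay between −4.19 and −4.17 and WT arrays between −4.45 and −4.22. With 7 Gy they averaged −0.79 ± 0.14 in KO-labelled arrays, with 4 lower and 2 higher (exact permutation adjusted p = 0.00899), and averaged 0.25 ± 0.15 in WT (0.0571). At 7 Gy they differed between labels by −0.54 ± 0.13, with 3 lower (exact permutation adjusted p = 0.00899), and their responses by −1.04 ± 0.21.

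Genes of other tissues did not rise with hepatocyte genes in WT. Lung genes fell by 0.73 ± 0.19 (1 of 4 called; exact permutation adjusted p = 0.0204), and muscle genes averaged 0.19 ± 0.71 (0.536), kidney genes −0.10 ± 0.49 (0.849), skin genes 0.13 ± 0.34 (0.805) and pancreas genes 0.03 ± 0.28 (0.833). The muscle genes Acta1 and Tnnt3 reached −0.71 and −0.64 in single KO-labelled arrays at 7 Gy, where the group means were −5.40 and −4.88. The muscle list stood at −2.94 and −2.89 in KO-labelled 7 Gy replicates 5 and 7 and between −7.22 and −5.89 in the others of that group. Acute phase genes of the liver rose by 1.88 ± 0.45 in KO-labelled arrays, with 8 of 16 higher and 1 lower (exact permutation adjusted p = 0.00899). Between labels they differed by 0.51 ± 0.50 at 0 Gy (exact permutation adjusted p = 0.536). This was 0.17 without KO-labelled 0 Gy replicate 5 and 0.67 without replicate 3. At 7 Gy they differed by −1.94 ± 0.42 (exact permutation adjusted p = 0.00899), or −0.38 ± 0.35 without WT 7 Gy replicates 3 to 5.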
